A study of Oryza sativa with 48 samples.

How the data were processed

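Total RNA of 48 rice leaf samples was labelled with Cy3 or Cy5 (200 ng per sample) and hybridised in pairs to 24 custom Agilent arrays on 8 slides, per the labels' protocols. Each channel was a sample of its own. The spots were read by Agilent Feature Extraction 10.5.1.1 with a 2-colour gene expression protocol, per the file headers. The deposited intensity columns used were the mean signal of each spot, the median of its local background and the processed signal, which per the file headers was background-subtracted, detrended and dye-normalized by the scanner software. Flags for spots well above background, saturated or non-uniform came from the same deposited files. The authors' deposited value table held log2 values of 125722 probes for the same 48 samples. Each of its columns had the rank order of the processed signal of its own channel (lowest rank correlation 0.99999902) and medians from 6.04 to 6.05, so its scale was log2 with columns quantile-normalized and probes not centred. Per the submitters' processing notes the tools were Agilent Feature Extraction 10.5.1.1 and affy, with no version given for the latter.

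Samples were grouped by days after transplanting as the labels give them. For 4 samples of the day 57 series taken after midnight the title and the sampling-date field gave different days, and the field was used. The labels describe no replicates, so all p-values rest on the deviation of samples from the fitted daily curve. Scan days, numbered 1 to 4, and slides came from the file headers: scan day 1 held all 13 day 44 samples and 7 of day 23, scan day 2 held 4 of day 23, scan day 3 held 1 of day 23, all 12 of day 78 and 5 of day 57, and scan day 4 held 6 of day 57. July and August were thus nearly separate in scanning.

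Of 156732 spots per array, 151878 were not controls. No spot was saturated. The 695 spots with a non-uniformity flag in any channel were left out, and spots of the same 60-base sequence were averaged, which left 148163 sequences. Background was corrected with normexp (offset 50) on mean and background signals, arrays were normalized within by loess, with weight 0 for controls and flagged spots, and between by Aquantile, and the channels were then separated. The 91190 probes well above background in at least 12 of the 48 samples were tested, and 60398 were well above background in all 48. The spike-in probes had an observed-to-expected slope of 0.902 to 0.930 (correlation 0.972 to 0.996), and spots of 1 sequence had an SD of 0.0847 to 0.193 log2 units within a channel. Intensities of different probes were not compared, apart from the medians of probe families.

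All samples entered 1 fit in limma 3.58.1 (R 4.3.3), with a mean and 24-h and 12-h cosine and sine terms of clock hour for each series, a dye term and the physical array as a random block (consensus correlation 0.242, from 5000 probes). The fit had 27 residual degrees of freedom. Moderated tests with an intensity trend were adjusted by Benjamini-Hochberg over all probes, at 0.05. A rhythm needed a fitted peak-to-trough range of at least 1 log2 unit and a level difference a change of at least 1. The level of a series is the mean of its fitted curve. Range and phase shifts over many probes were given a jackknife standard error over the 12 clock hours. Peak hours were put in 2-h bins centred on the sampled hours.

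On simulated data with 20000 probes, real means and residual spreads and seeded changes, the day 44 against day 23 test found 83.6% of changes of 0.5 log2 units, 97.0% of those of 1 and all of those of 2 (100%), with 20 of 19800 unchanged probes called. For rhythm at day 23 it found 77.6%, 97.0% and 100% of ranges of 1, 2 and 4 log2 units, with 27 of 19600 unchanged probes called. In both of these tests the unchanged probes made up more than the nominal share of the calls. For the rhythm difference of day 78 against day 57 it found 43.3%, 82.1% and 98.5% of rhythms of 1, 2 and 4 log2 units shifted by 4 h, with 5 of 19800 unchanged probes called. These simulated tests went by the adjusted p alone, without the minimum change or range.

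The named-probe rule, set before the data were examined, took the probes with the largest change among those past the threshold with the same sign at every clock hour sampled in both series, and required a gene symbol or description. The files give none, and the reference gene table (178 list genes, 0 of whose IDs occur in a probe name) holds no sequences. After this was seen, the same ranking was used without that condition, limited to 2 probes up and 2 down. A probe was skipped when 1 of its ends matched the opposite end of an earlier one over at least 10 bases. A stretch shared inside a probe was no ground for skipping. For rhythm the probe of widest mean range in each peak-time group was taken, and for rhythm differences the probes with the largest root mean square difference. 1 probe that this ranking gave for a rhythm difference is not reported here. The tests of 17 gene lists, their set-test alternatives and the choice of the brightest probe of a gene were therefore not run. The coordinates of probes are not given in the sources used here.

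Alternatives fixed before the data were examined were quantile normalization and 75th-percentile scaling of log2 processed signals, the authors' value table, no background subtraction, no filter or a filter on all 48 samples, slide as a fixed block, no array block, no dye term, 24-h terms alone, clock hours common to all series, no minimum change, and clock hour and day as a block. Added after seeing the data were scan day as a fixed block, comparisons within a scan day, 1 probe per group of probes overlapping by at least 30 bases, each clock hour left out in turn, the 10:00 repeat with the dye effect subtracted, and a count of probes whose 2 highest samples of a series were the channels of 1 array, at least 3 log2 units above the others. Splits of the samples were drawn 100 times with a fixed seed, in fits of the 2 compared series (all 4 for the interaction) without the array block, and clock hours were permuted 50 times within each series.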

Results

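Gene expression was measured in leaves of rice (Oryza sativa, variety Koshihikari, a japonica table rice) grown in a paddy field in Fukuoka in 2014 under ordinary cultivation. Seedlings were transplanted on 4 June or on 25 June, and leaves of each planting were taken at 2-h intervals over a day, once on 18 to 19 July and once on 21 to 22 August. This gave 4 series named here by the days from transplanting to sampling: day 23 with 12 samples and day 44 with 13 in July, day 57 with 11 and day 78 with 12 in August. The day 23 series held no sample at 20:00, the August series held none at 04:00, and the day 57 series held no second 10:00 sample. Each time point was a single sample, so the spread behind every test was the deviation of the samples from a smooth daily curve and not a spread between replicate plants. The 48 samples were hybridised in pairs to 24 two-colour microarrays, each channel being its own sample, with 151878 gene probes of 60 bases. Between 70557 and 95992 of them were well above background in a sample, with a mean of 81322 in the day 23, 83528 in the day 44, 91588 in the day 57 and 91049 in the day 78 series. These numbers also followed the scan day. On scan days 1 to 4 the mean was 79742, 78850, 90353 and 91430 in Cy3 channels. In Cy5 channels it was 85844, 81436, 91129 and 92569. July and August were nearly separate in scanning, so these numbers do not tell month from scan day. The number of arrays limits the precision of every value below.

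The files name probes only by an ID and give their sequence, and they do not pair the probes with genes. Results are therefore given per probe, as counts of probes grouped by the hour of their peak, with at most 2 probes that rose and 2 that fell named by ID and sequence in each comparison. The 2 named probes of a direction may measure the same transcript, which was not tested, so they are not separate findings. No probe could be tested as a member of the 17 gene lists fixed beforehand.

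The clock hour was the main axis along which the leaves differed. The first 2 principal components, with 39.3% and 23.4% of the variance of 91190 tested probes, placed the samples of every series on a ring in the order of the clock. Component 3, with 14.0%, parted the months, with every August sample above 0 and every July sample below 0 except 3 of day 44 taken from 10:00 to 14:00. The months were nearly separate in scanning, so this component does not tell month from scan day. The second 10:00 sample of day 23, scanned with August, lay at -14.2 and the first at -63.0. Within a series, the standard deviation (SD) over probes of the log2 difference between 2 samples grew from 0.423 in the day 23, 0.430 in the day 44, 0.411 in the day 57 and 0.438 in the day 78 series at 2 h apart to between 1.06 and 1.08 at 12 h apart, and fell again towards 24 h.

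**Figure D1:**
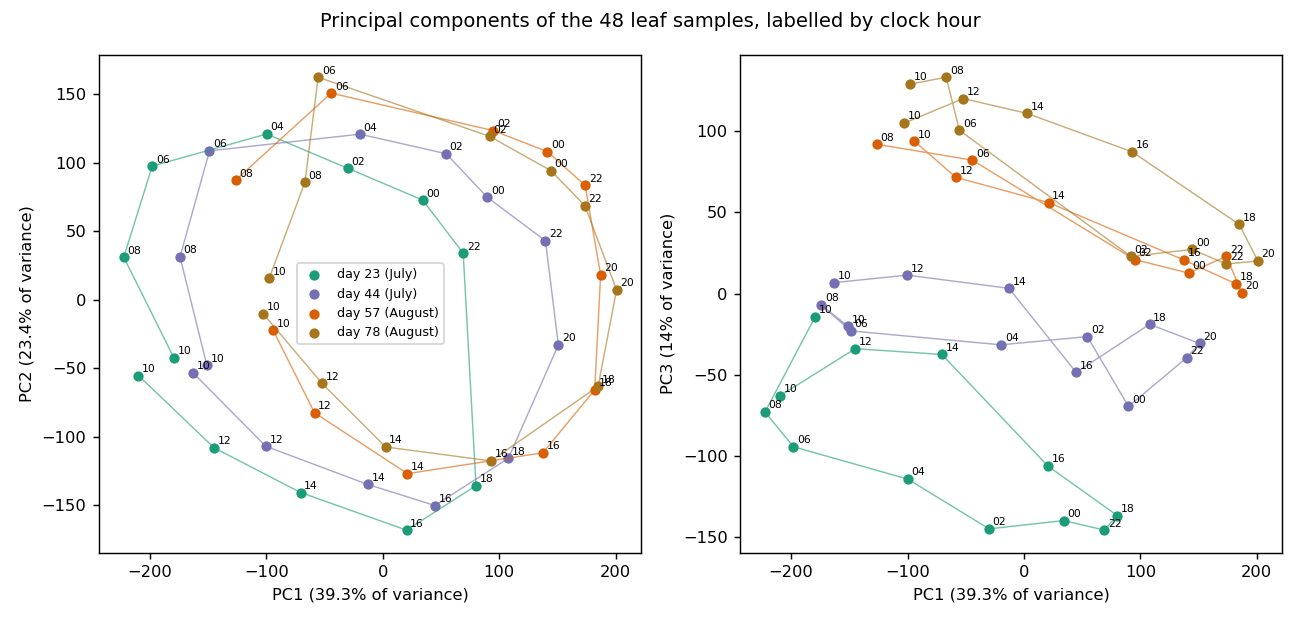
Principal component scores of the 48 leaf samples from normalized log2 intensities of 91190 probes, with the first component on the horizontal axis and component 2 (left) or 3 (right) on the vertical axis. Points are samples coloured by series and numbered by clock hour, and lines join samples in the order they were taken. The rings on the left show the daily course. The right panel shows the separation of July and August, which were nearly separate in scanning too.

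**Figure D2:**
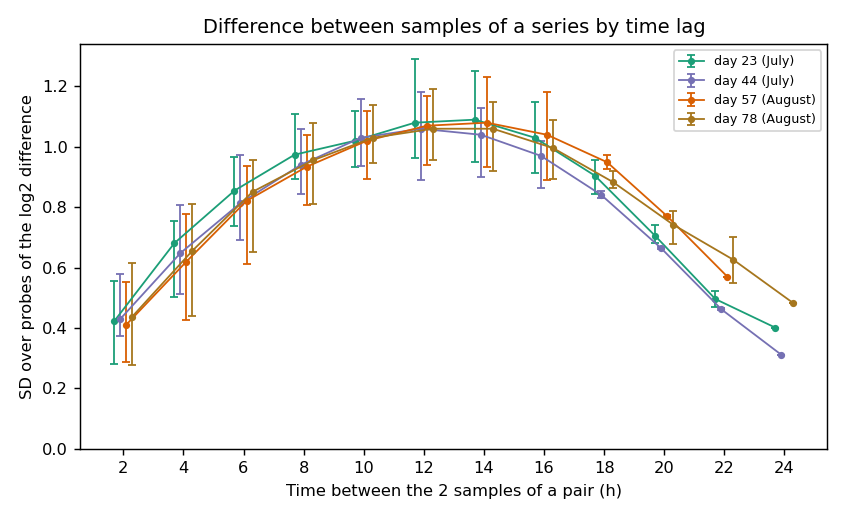
Mean SD over probes of the log2 difference between 2 samples of a series (vertical axis) against the hours between them (horizontal axis), with bars from the lowest to the highest pair at that lag. All 4 series rise to above 1 at 12 h and fall to between 0.311 and 0.482 at 24 h in the 3 series that have such a pair.

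The first question of the series was how expression varied over a day. Between 36263 and 40560 probes were rhythmic in a series, 24523 (26.9% of those tested) were rhythmic in all 4 series and 53904 (59.1%) in at least 1. The counts were 40560 at day 23, 36263 at day 44, 37337 at day 57 and 38605 at day 78, with a median peak-to-trough range of 1.66, 1.65, 1.63 and 1.64 log2 units in that order. Probes with a range of at least 3 log2 units, which is an 8-fold change within a day, numbered 5780, 4977, 5274 and 5290. A 12-h component wider than the 24-h component was found in 1076 rhythmic probes at day 23, 565 at day 44, 790 at day 57 and 1751 at day 78, which is at most 4.54% of them. Rhythm was tested with limma's moderated F test on the 24-h and 12-h terms of each series, at an adjusted p of 0.05 and a fitted range of at least 1 log2 unit. Overlapping probes of 1 transcript are counted separately, and the 24523 probes fell into 17146 groups of overlapping sequences.

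Peaks gathered in the early morning and in the afternoon in the first 3 series. At day 23, 12.5% of rhythmic probes peaked in the 2-h bin at 08:00 and 11.5% in that at 16:00, at day 44 14.3% and 13.9%, and at day 57 12.0% and 13.2%. The day 78 series had 8.35% and 8.42% in these bins, and its fullest bin was that at 22:00 with 13.7%, against 6.49%, 7.66% and 5.01% in the series of day 23, day 44 and day 57. Probes peaking from 20:00 to 02:00 made up 35.6% of rhythmic probes at day 78 against 24.9% at day 57 in the same 2 days. These shares have no test of their own, since probes are not independent replicates.

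**Figure D3:**
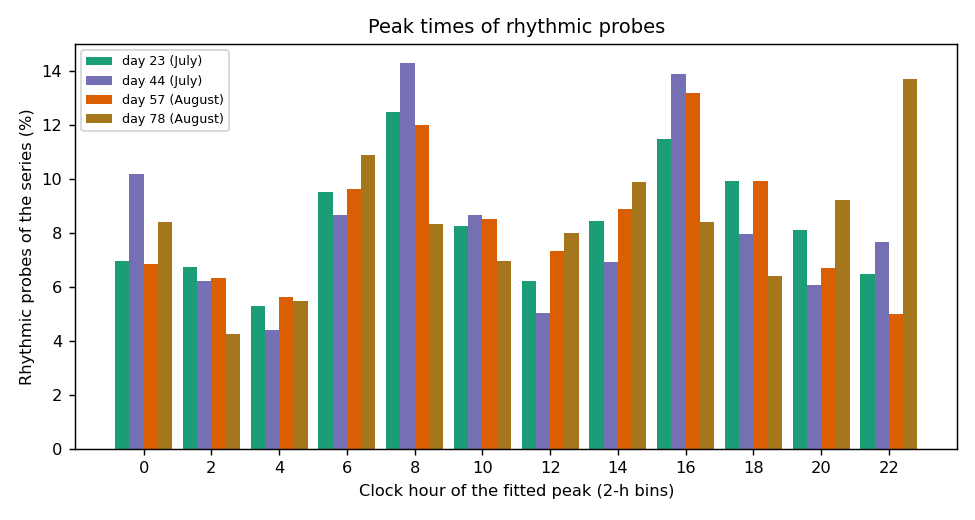
Share of the rhythmic probes of each series (vertical axis, percent) whose fitted peak lay in each 2-h bin of clock hour (horizontal axis), with bars coloured by series. The series of day 23, day 44 and day 57 have high bars at 08:00 and 16:00, and the day 78 series has its highest bar, 13.7%, at 22:00.

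The probe with the widest mean range was taken from each of the 4 peak-time groups, with ranges and peak hours read from the fitted curves. Of the probes peaking from 04:00 to 08:00, eAry2_26025 (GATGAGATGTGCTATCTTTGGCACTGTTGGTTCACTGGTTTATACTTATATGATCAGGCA) had a mean range of 10.71 log2 units and peaked at 7 h at day 23, 7.5 h at day 44, 9 h at day 57 and 9.5 h at day 78. Among those peaking from 10:00 to 12:00, 44kb3_38952 (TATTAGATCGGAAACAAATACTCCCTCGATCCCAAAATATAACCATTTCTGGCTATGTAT) had a mean fitted range of 11.35 log2 units. Its fitted peak lay at 11.5 h at day 44, at 12.5 h in both August series and earlier at day 23. Its samples formed a plateau from 08:00 to 16:00, with the highest at 16:00 at day 23, day 57 and day 78. In each series its fitted range was wider than the span of the samples, so neither this range nor a noon peak was observed as such. In the group peaking from 14:00 to 18:00, eAry2_48790 (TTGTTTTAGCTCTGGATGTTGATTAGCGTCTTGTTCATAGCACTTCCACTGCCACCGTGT) ranged over 11.48 log2 units and peaked between 15.5 and 16.5 h. In the night group, eAry2_28990 (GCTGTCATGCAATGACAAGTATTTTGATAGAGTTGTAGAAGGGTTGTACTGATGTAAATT) ranged over 9.59 log2 units, peaked between 1.5 and 3 h, and was well above background in 37 of 48 samples. The highest limma adjusted p of these 4 probes in any series was 4.82e-07, for 44kb3_38952 at day 23.

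**Figure D4:**
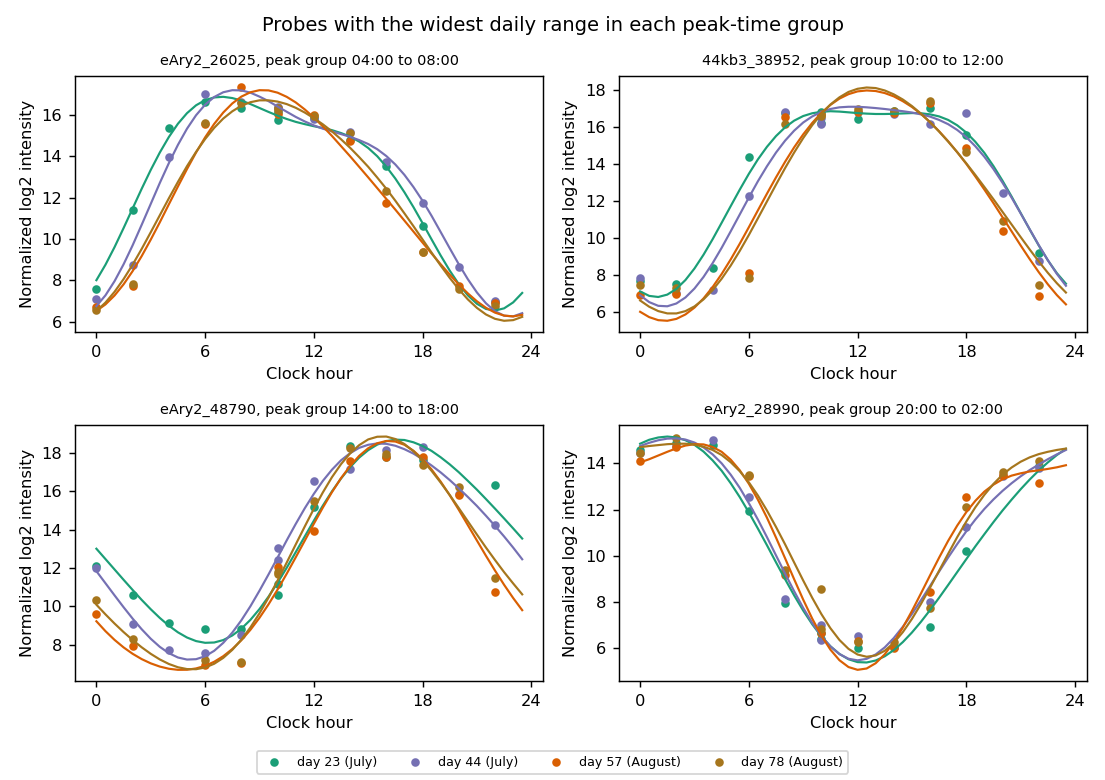
Normalized log2 intensity (vertical axis) against clock hour (horizontal axis) for the probe with the widest mean range in each of the 4 peak-time groups. Points are samples coloured by series and lines are the fitted curves; the fitted range of a probe within a series runs from 9.21 to 12.43 log2 units.

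In July, leaves of the earlier planting were compared with those of the later planting on the same days (day 44 against day 23). In leaves of the earlier planting 1949 probes were lower and 1000 higher by at least 1 log2 unit, together 3.23% of the probes. The balance moved with the processing: 33.9% of the called probes were higher here, 48.8% of 7640 with quantile normalization, 46.6% of 6471 with the authors' values and 57.2% of 44763 with no minimum change. 44kb3_27553 (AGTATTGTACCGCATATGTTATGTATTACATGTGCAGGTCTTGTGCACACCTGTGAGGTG) fell from a mean of 14.40 at day 23 to 7.94 at day 44, an 88.0-fold difference (log2 change -6.46, SE 0.354, adjusted p = 3.52e-14), and 44kb3_20070 (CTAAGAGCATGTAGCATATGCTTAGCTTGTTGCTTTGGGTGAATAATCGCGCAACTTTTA) was 78.2-fold lower. Cuffnpc_00332 (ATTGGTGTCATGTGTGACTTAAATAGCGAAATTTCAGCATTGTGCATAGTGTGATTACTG) rose 15.3-fold, from 7.21 to 11.15 (log2 change 3.94, SE 0.231, adjusted p = 1.03e-13), and 44kb3_23620 (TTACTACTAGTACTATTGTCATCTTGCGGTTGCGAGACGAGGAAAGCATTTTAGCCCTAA) rose 14.4-fold. All 4 differed in the same direction at each of the 11 clock hours sampled in both series. The rule for naming probes required this, so it is not separate evidence for the 4 differences. Of probes rhythmic in all 4 series, those peaking from 10:00 to 12:00 had 26 higher and 216 lower among 4093, and those peaking from 20:00 to 02:00 had 138 higher and 130 lower among 6837. Those peaking from 04:00 to 08:00 had 92 higher and 250 lower among 6086, and those peaking from 14:00 to 18:00 had 86 and 124 among 7507. In no comparison were the peak-time groups tested against each other or recounted under another normalization.

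The tests were limma's moderated tests on the means of the fitted daily curves. Within scan day 1, which held both series at 7 matched hours, 2316 probes passed, and all 2949 probes had the same direction as over all samples, though these samples were part of the fit that called them. With scan day as a block 2853 probes passed and with the 8 slides as a block 169, and of the 2949 called here 2604 and 124 stayed past the adjusted p in the same direction.

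In August, leaves of the earlier planting were again compared with those of the later planting (day 78 against day 57). Here 426 probes were higher and 880 lower at day 78, 1.43% of those tested, a smaller count than in July, though with slide as a block the order turned (821 in August and 169 in July). The balance turned too, since 32.6% of the called probes were higher here, 57.5% with slide as a block and 51.8% of 14859 with no minimum change. 44kb3_24139 (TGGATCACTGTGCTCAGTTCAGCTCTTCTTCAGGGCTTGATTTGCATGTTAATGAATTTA) rose 29.5-fold, from 7.85 to 12.73 (log2 change 4.88, SE 0.542, limma adjusted p = 1.02e-07), and 44kb3_31676 (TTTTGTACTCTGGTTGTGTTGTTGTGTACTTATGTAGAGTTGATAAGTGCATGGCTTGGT), which was well above background in 6 of 11 samples at day 57 and in all 12 at day 78, rose 19.9-fold. Under the alternatives their log2 changes ran from 4.67 to 7.42 and from 3.45 to 6.60. eAry2_37720 (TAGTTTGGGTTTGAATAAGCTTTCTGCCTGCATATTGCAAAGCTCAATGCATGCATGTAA) fell from 14.48 to 9.89, a 24.1-fold difference (log2 change -4.59, SE 0.304, limma adjusted p = 3.18e-12), and 44kb3_9873 (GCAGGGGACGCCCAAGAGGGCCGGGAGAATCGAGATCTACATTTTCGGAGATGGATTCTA) was 18.9-fold lower. No peak-time group of probes rhythmic in all 4 series had over 1.05% of its members lower or over 0.831% higher.

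Within scan day 3, which held both series at 5 matched hours, 731 probes passed and 1303 of the 1306 probes had the same direction, though these samples were part of the fit that called them. Of the 1306, 538 stayed past the adjusted p in the same direction with scan day as a block (813 probes passed in all) and 250 with slide as a block (821 in all), where the log2 change of eAry2_37720 was -4.21 (adjusted p = 0.0627) and that of 44kb3_9873 was -3.69 (adjusted p = 0.0582) with wider standard errors.

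Across all probes the July and August differences between plantings were nearly uncorrelated, while the called probes overlapped in both the same and the opposite direction. Across 91190 probes, which are not independent replicates, the differences of the 2 months correlated at Pearson's r = 0.0458 and Spearman's rho = 0.0641. Of the called probes 59 were higher and 89 lower in both months, where independent lists would share 4.67 and 18.8, and 129 were higher in July and lower in August and 58 the reverse, where independent lists would share 9.65 and 9.10. The interaction, the August difference minus the July difference, passed limma's test at 4358 probes, 2257 positive and 2101 negative. Of the positive ones 1343 were also called in July and 271 in August, and of the negative ones 649 and 652. eAry1_43442 (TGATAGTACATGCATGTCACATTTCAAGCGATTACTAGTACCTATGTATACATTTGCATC) was higher in the earlier planting in July and lower in August (log2 changes of 2.01 and -3.95), with an interaction of -5.96 (SE 0.337, limma adjusted p = 1.34e-13). 44kb3_24139 went the other way, with log2 changes of -1.79 and 4.88. With scan day as a block 3969 probes passed and with slide as a block 1505, and of the 4358 called here 2556 and 531 stayed past the adjusted p in the same direction. With either slide or scan day as a block the correlation of the differences was below 0, at -0.282 and -0.0635.

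For the earlier planting, August was compared with July (day 78 against day 44). 1927 probes were higher and 2418 lower in August, 4.76% of those tested. The balance turned with the processing: 44.3% of the called probes were higher here, 53.5% of 11482 with quantile normalization, 50.1% of 9088 with the authors' values and 54.4% of 44860 with no minimum change. 44kb3_10988 (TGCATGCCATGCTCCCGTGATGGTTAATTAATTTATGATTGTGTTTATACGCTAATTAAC) rose 45.7-fold, from 6.41 to 11.93 (log2 change 5.51, SE 0.137, limma adjusted p = 4.74e-23), being well above background in 4 of 13 samples at day 44 and in all 12 at day 78 and ranging from 3.91 to 7.96 log2 units under the alternatives, and eAry2_44367 (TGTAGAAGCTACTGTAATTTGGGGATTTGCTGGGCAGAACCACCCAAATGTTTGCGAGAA) rose 39.5-fold. 44kb3_785 (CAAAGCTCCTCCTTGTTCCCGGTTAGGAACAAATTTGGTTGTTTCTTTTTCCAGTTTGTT) fell from 13.83 to 7.94, a 59.4-fold difference (log2 change -5.89, SE 0.329, limma adjusted p = 6.51e-15), and eAry1_16687 (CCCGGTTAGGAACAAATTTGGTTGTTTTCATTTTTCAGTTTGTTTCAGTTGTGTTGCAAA), which shares a stretch of 27 bases with it, was 45.1-fold lower. Of the 6837 probes with a peak from 20:00 to 02:00, 418 were higher and 114 lower, and of the 4093 with a peak from 10:00 to 12:00, 70 were higher and 301 lower. The 6086 with a peak from 04:00 to 08:00 had 187 higher and 260 lower, and the 7507 with a peak from 14:00 to 18:00 had 83 and 208.

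No scan day held samples of both series, so no within-batch value exists. With scan day as a block, tied together through other series, 1530 probes passed, and with slide as a block 115, where the log2 change was -5.34 for 44kb3_785 (adjusted p = 0.134) and -3.66 for eAry1_16687 (adjusted p = 0.309) and the median SE over the called probes rose from 0.161 to 0.782. Of the 4345 called here 1084 and 95 stayed past the adjusted p in the same direction.

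**Figure D5:**
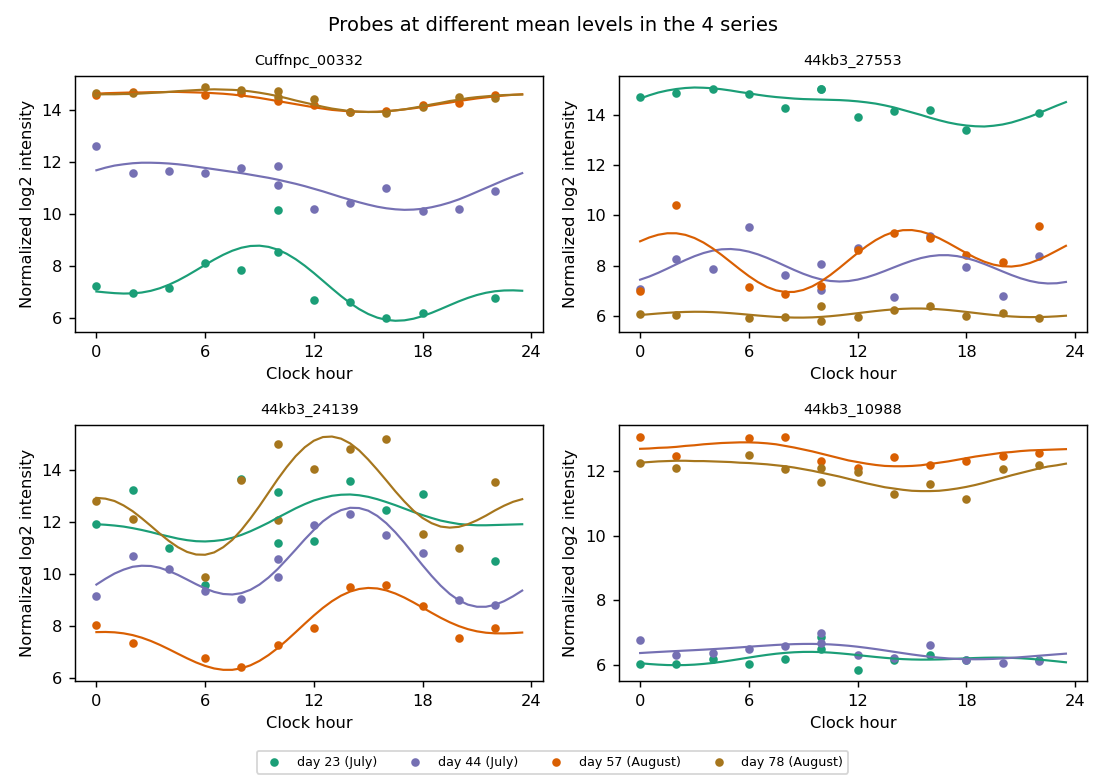
Normalized log2 intensity (vertical axis) against clock hour (horizontal axis) for 4 named probes whose mean level differed between series, with points for samples and lines for the fitted curves. Cuffnpc_00332 lies near 7.21 at day 23, 11.15 at day 44 and 14.36 at day 57, and 44kb3_10988 lies at 6.41 at day 44 and 11.93 at day 78.

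For the later planting, August was compared with July (day 57 against day 23), the pair with the largest of the 4 counts. 3333 probes were higher and 4862 lower in August, 8.99% of those tested. The balance turned with the processing, since 55.7% of 17871 called probes were higher with quantile normalization, 54.1% of 14897 with the authors' values and 57.3% of 59368 with no minimum change. Cuffnpc_00332 and 44kb3_23620, which were also higher at day 44 than at day 23, were 142-fold (log2 change 7.16, SE 0.243, limma adjusted p = 3.04e-20) and 132-fold higher. Under the alternatives their log2 changes ran from 4.70 to 8.70 and from 3.88 to 8.06, and they were well above background in 9 and 10 of the 12 day 23 samples. eAry1_47512 (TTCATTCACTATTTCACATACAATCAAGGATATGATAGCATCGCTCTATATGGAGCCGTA) fell from 12.85 to 6.77, a 67.5-fold difference (log2 change -6.08, SE 0.372, limma adjusted p = 1.99e-14), and was well above background in 5 of 11 samples at day 57, with log2 changes from -8.59 to -4.36 under the alternatives. 44kb3_20070, lower at day 44 too, was 64.7-fold lower. Probes that peaked from 10:00 to 12:00 were lower in 835 of 4093 cases (20.4%) and higher in 32, and of those peaking from 20:00 to 02:00, 697 of 6837 (10.2%) were higher and 165 lower. The 6086 with a peak from 04:00 to 08:00 had 257 higher and 708 lower, and the 7507 with a peak from 14:00 to 18:00 had 280 and 416.

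The changes of the 2 plantings between July and August correlated across probes at Pearson's r = 0.627 and Spearman's rho = 0.602. They have no sample in common but share the difference between the July and August scan days, which neither this correlation nor the shared counts take out. 918 probes were higher and 1615 lower in both, where independent lists would share 70.4 and 129. Scan day 3 held the day 57 samples from 10:00 to 18:00 and the second 10:00 sample of day 23: against that sample, 96.9% of the 8195 probes differed in the same direction at 10:00 at day 57 and 57.6% did so by over 2-fold, though both samples were part of the fit that called these probes. With scan day as a block 3112 probes passed, and with slide as a block 3290, where the log2 change of eAry1_47512 was -4.36 (adjusted p = 0.128). Of the 8195 called here 2546 and 1624 stayed past the adjusted p in the same direction.

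The shape of the fitted daily curve was compared with its mean taken out. A probe near background in a series can show only a narrow range there, so the comparison is not free of level. The shape differed in 3219 probes between day 44 and day 23, in 52 between day 78 and day 57, in 5046 between day 78 and day 44, and in 9238 between day 57 and day 23. At an unadjusted p of 0.05 of the same limma test, the numbers were 16915, 8176, 19649 and 24048 in that order. Of the 9238, 2451 were rhythmic at day 23 only of the 2 series and 1238 at day 57 only, and 37.1% had the wider range at day 57. Of the 52, 29 had the wider range at day 78. Of the 3219, 877 were rhythmic at day 23 only of the 2 series and 467 at day 44 only. eAry2_24490 (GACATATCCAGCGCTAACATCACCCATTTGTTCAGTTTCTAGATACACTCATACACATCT) ranged over 6.56 log2 units at day 23 and 0.231 at day 57 (limma adjusted p = 0.00102), where it was well above background in 2 of 11 samples. eAry2_37557 (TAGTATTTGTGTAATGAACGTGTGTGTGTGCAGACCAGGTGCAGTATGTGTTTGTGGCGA) ranged over 9.76 log2 units at day 44 with a peak at 10 h and over 0.619 at day 78 (limma adjusted p = 0.000122), and maskBest_01467 (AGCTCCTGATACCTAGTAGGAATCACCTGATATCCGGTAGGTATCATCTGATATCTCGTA) did the reverse, with 0.446 and 9.66 log2 units. At day 78 maskBest_01467 stood at 14.55 and 18.64 at 20:00 and 22:00, the 2 channels of 1 array, and between 6.38 and 7.34 in the other 10 samples, so its range rests on that array. Where their ranges were narrow, both probes were dim. eAry2_37557 had a mean of 6.42 at day 78, with 8 of 12 samples well above background (8 of 13 at day 44). maskBest_01467 had a mean of 6.70 at day 44, with 5 of 13 samples well above background. In the July pair, eAry1_19909 (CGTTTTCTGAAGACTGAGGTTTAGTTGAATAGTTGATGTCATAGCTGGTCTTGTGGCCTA) ranged over 7.66 log2 units at day 44 and 1.02 at day 23 (limma adjusted p = 0.0438). At day 23 its mean was 6.48, with 3 of 12 samples well above background. Its range at day 44 also rests on 1 array, with 13.42 at 14:00 and 16.57 at 16:00 and between 6.20 and 7.62 in the other 11 samples. Such a pair of samples at least 3 log2 units above all others of its series was found in 11 of the 3219 probes, 0 of the 52, 3 of the 5046 and 9 of the 9238, a check added after seeing the data. eAry2_31397 (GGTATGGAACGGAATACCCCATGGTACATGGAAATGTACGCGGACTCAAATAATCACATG) ranged over 4.51 log2 units at day 44 and 7.88 at day 23 (limma adjusted p = 0.0182), and eAry1_44137 (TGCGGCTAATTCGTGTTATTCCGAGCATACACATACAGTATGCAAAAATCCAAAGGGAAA) over 7.90 at day 78 and 5.16 at day 57 (limma adjusted p = 0.0161), with peaks at 21 h and 21.5 h. 44kb3_31635 (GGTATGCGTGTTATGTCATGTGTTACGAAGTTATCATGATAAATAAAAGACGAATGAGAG) ranged over 4.99 log2 units at day 57 with a fitted peak at 15.5 h and over 3.19 at day 23 with a fitted peak at 21 h (limma adjusted p = 0.0177). Its highest day 23 sample was at 08:00, that at 22:00 was nearly as high, and the series has no 20:00 sample. The samples therefore do not settle the day 23 peak hour of this probe.

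Over the 24523 probes rhythmic in all 4 series, the 24-h peak lay a median of 0.413 h later at day 78 than at day 57 (jackknife SE 0.174 over 12 clock hours). The median shift was 0.180 h (SE 0.145) for day 44 against day 23, 0.210 h (SE 0.197) for day 78 against day 44 and -0.0395 h (SE 0.152) for day 57 against day 23. These counts moved with the fit: in the order of the counts above they were 1343, 4, 4301 and 673 with scan day as a block, 82, 5, 49 and 666 with slide as a block, and 10709, 1107, 14495 and 21001 without the array block. Leaving out 1 clock hour gave from 1154 (08:00) to 4198 (02:00) for day 44 against day 23, from 18 (00:00) to 326 (10:00) for day 78 against day 57, from 1842 (08:00) to 7248 (02:00) for day 78 against day 44, and from 5129 (18:00) to 11658 (10:00) for day 57 against day 23.

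Leaves taken at 10:00 on consecutive days gave the only repeat of a clock hour. The SD over probes of the log2 difference was 0.311 at day 44, 0.401 at day 23 and 0.482 at day 78, with correlations across probes of 0.991, 0.986 and 0.979. At day 44 the repeat lay below the mean of 12 pairs 2 h apart (0.430), at day 23 below the mean of 10 (0.423), and at day 78 above the mean of 10 such pairs (0.438). At day 78, 2252 probes were at least 2-fold higher and 1992 at least 2-fold lower on the second day, against 575 and 695 at day 44 and 992 and 1342 at day 23. The day 44 pair had the same dye and the others did not. The day 23 samples were scanned on scan days 1 and 3, while the day 44 and day 78 pairs each shared a scan day. With the fitted dye effect subtracted, an alternative chosen after seeing the data, the SD was 0.311, 0.372 and 0.436 in the same order of day 44, day 23 and day 78. The day 78 value then no longer lay above 0.438, though the pairs 2 h apart were not so adjusted. The order of the series depended on the normalization: with quantile normalization the SD was 0.545 at day 44, 0.810 at day 23 and 0.699 at day 78.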

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

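The tests of scan day for the difference between day 57 and day 23, and the splits of the samples for day 78 against day 57, were chosen after the results were seen, and scan day as a block was added after the data were examined.

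The difference between the plantings differed between July and August, by a test of the difference itself. The level interaction passed at 4358 probes and the rhythm interaction at 486 (12719 at an unadjusted p of 0.05). 44kb3_24139 had an interaction of 6.67 log2 units and eAry1_49681 (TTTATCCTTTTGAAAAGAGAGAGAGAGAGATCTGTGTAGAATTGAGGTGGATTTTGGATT) one of 5.37, both lower in the earlier planting in July and higher in August. eAry1_43442 had an interaction of -5.96 and eAry1_15483 (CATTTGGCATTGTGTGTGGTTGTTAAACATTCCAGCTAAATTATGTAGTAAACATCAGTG) one of -5.85, both higher in July and lower in August. Differences between slides remain open as a source. With slide as a block 1505 probes passed, and 531 of the 4358 stayed past the adjusted p in the same direction. The median SE over these 4358 rose from 0.252 to 0.855, while the size stayed (slope 1.05 on the value without the block, 90.5% of the called probes in the same direction). A wider error and a slide effect could each lose calls, and the 2 cannot be told apart. Plant age and season, which differ between the series by design, remain open and were not tested.

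The mean level of 8195 probes differed between day 57 and day 23, and 11 of the 12 day 23 samples were scanned on days that held no day 57 sample. If scan day were the whole source, day 44, scanned with most of day 23, would lie at the day 23 level. The median position of day 44 was 0.520 of the way from day 23 to day 57 (jackknife SE 0.0554), with 95.1% of these probes on the day 57 side. Both distances start from the day 23 mean that also chose these probes. An error or slide shift in day 23 alone would move day 44 to that side too, and no value without change was computed. This position therefore cannot settle scan day as a source. Dim probes are argued against, since 8.70% were called among probes well above background in all 48 samples, against 8.99% of all tested. A part of the size may still come from scanning: the second 10:00 sample of day 23, scanned with August, moved from the first with a slope of 0.273 on the difference, and the day 57 sample lay at a slope of 0.780 from it. With slide as a block 1624 of the 8195 stayed past the adjusted p in the same direction, and the median SE over them rose from 0.159 to 0.584 before this cut. Age, season, slides and the scan-day share of the size remain open.

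Rhythm differences between the plantings were more numerous in July (3219) than in August (52). At an unadjusted p of 0.05 limma's moderated F test gave 16915 probes (18.5%) in July and 8176 (8.97%) in August. The size of the contrast thus depends on the cut-off. Scan days that followed the clock hours of day 23 do not alone account for the July count, since with scan day as a block 1343 probes passed. The August count was then 4. The day 57 samples were on scan day 3 from 10:00 to 18:00 and on scan day 4 from 20:00 to 08:00. This block therefore also takes up part of their daily course, and the August count with it is no fair measure of the contrast. For a wider residual spread in August, the median spread at day 57 (0.110) was 0.889 of that at day 23 (0.124), though it was 0.139 at day 78 and 0.129 at day 44. The fit used 1 residual spread for all 4 series, so this ratio cannot decide the question. Slides remain open, with 82 and 5 probes when slide was a block, and the August count was within what other splits of the samples gave. Plant age and season, which differ by design, remain open and were not tested.

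Each comparison was set against 100 splits of the samples of its series, the real one included, in fits of the compared series alone and without the array block, so the real counts differ from those of the fit over all samples without that block. The splits treat samples as interchangeable and take no account of array, slide or scan day. Labels were drawn over all clock hours, so a real difference between series entered the residual of the other splits. The samples are a time course and not interchangeable, so a low count in the other splits does not exclude chance. For level, 1 split, the real one, gave as many probes in each comparison: 3021 against a highest other of 1320 for day 44 and day 23, 1288 against 521 for day 78 and day 57, 4392 against 272 for day 78 and day 44, 8245 against 4399 for day 57 and day 23, and 4345 against 39 for the interaction. For rhythm differences 1 split did so for day 44 and day 23 (7176 against 3401), day 78 and day 44 (6815 against 2465) and day 57 and day 23 (19067 against 11877). For day 78 and day 57, 7 of 100 splits gave at least the real 69 probes, with a highest of 667, so chance cannot be excluded. A split that calls several times the real count points to a structure among the samples, which was not tested. Of 50 orders of the clock hours within a series, 1, the real one, gave as many rhythmic probes: 41783 against a highest other of 0 at day 23, 36959 against 51 at day 44, 38623 against 15636 at day 57 and 37061 against 0 at day 78.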

How the results depend on the processing

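Scan day as a block, comparisons within a scan day, 1 probe per group of overlapping probes, each clock hour left out and the dye-subtracted repeat were chosen after seeing the data; the other alternatives were fixed beforehand. The counts of rhythmic probes stayed within 1.5 times under every alternative run except no minimum change. Of 408 values of the 16 named level results under alternatives, 403 kept their direction and side of the threshold, 5 lost the threshold with slide as a block (highest adjusted p 0.309) and 0 reversed. These results were picked for the largest changes with 1 sign at every matched hour, so they do not speak for all called probes. With slide as a block 124 of 2949, 250 of 1306, 95 of 4345 and 1624 of 8195 called probes stayed past the adjusted p in the same direction, in the order of the level counts below. Counts of level and rhythm differences moved most, and except where the alternative tests fewer probes or drops the minimum change, the cause was not tested. No background subtraction, and clock hour and day as a block at matched times for the level counts, moved no count by over 1.5 times. Quantile normalization shifted the median of all probes for day 57 against day 23 to 0.107 log2 units, against 0.0606. Gene-based alternatives (brightest probe of a gene, set tests) were not run for want of gene names. Signal over background limits the dim probes, which single samples often did not measure.

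Level counts are given in the order day 44 against day 23, day 78 against day 57, day 78 against day 44, day 57 against day 23 and the interaction. With 75th-percentile scaling they were 6965, 3436, 11174, 16869 and 8642, with quantile normalization 7640 (48.8% higher, against 33.9%), 3074, 11482, 17871 (55.7% higher, against 40.7%) and 8923, and with the authors' values 6471 (46.6% higher), 2665, 9088, 14897 (54.1% higher) and 7779. With no minimum change they were 44763 (57.2% higher), 14859 (51.8%, against 32.6%), 44860 (54.4%, against 44.3%), 59368 (57.3%) and 31744. With only probes well above background in all 48 samples they were 1796, 811, 2828, 5261 and 2681. With slide as a block they were 169, 821 (57.5% higher), 115, 3290 and 1505. With scan day as a block the second to the fourth were 813, 1530 and 3112. Within scan day 3 day 78 against day 57 gave 731, and with 1 probe per overlap group day 44 against day 23 gave 1950. The correlation of the July and August differences reversed to -0.0635 with scan day and -0.282 with slide as a block.

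With no minimum change 67784 probes were rhythmic at day 23, 64740 at day 44, 61113 at day 57 and 64144 at day 78. The SD of the 10:00 repeat was 0.728 at day 23 and 0.538 at day 44 with 75th-percentile scaling, 0.810 and 0.545 with quantile normalization, and 0.761 and 0.523 with the authors' values.

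Rhythm differences between day 44 and day 23 numbered 1205 with 24-h terms only, 1820 with 75th-percentile scaling, 10709 without the array block, 1343 with scan day and 82 with slide as a block, and 1449 with probes well above background throughout. Leaving out 1 clock hour gave 1154 to 4198, with 1477 without 00:00, 1154 without 08:00, 1969 without 12:00, 1510 without 18:00 and 1280 without 22:00. Between day 57 and day 23 they numbered 5129 with 24-h terms only, 21001 without the array block, 5749 with 1 probe per overlap group, 673 with scan day and 666 with slide as a block, and 5664 with the authors' values. Leaving out 1 clock hour gave 5129 to 11658, with 5764 without 08:00, 5301 without 14:00, 5129 without 18:00 and 5545 without 22:00. Between day 78 and day 44 they numbered 1263 with 24-h terms only, 14495 without the array block, 3213 with 1 probe per overlap group, 49 with slide as a block and 3220 with the authors' values. Leaving out 1 clock hour gave 1842 to 7248, with 2537 without 00:00, 1842 without 08:00, 2699 without 18:00 and 2892 without 22:00. Between day 78 and day 57 they numbered 6 with 24-h terms only, 25 with 75th-percentile scaling, 1107 without the array block, 85 without the dye term, 402 with no filter, 97 with common clock hours, 29 with 1 probe per overlap group, 23 with quantile normalization, 4 with scan day and 5 with slide as a block, 24 with the authors' values and 23 with probes well above background throughout. Leaving out 1 clock hour gave 18 to 326, with 18 without 00:00, 176 without 02:00, 169 without 06:00, 27 without 08:00, 326 without 10:00, 24 without 12:00, 31 without 16:00 and 29 without 22:00.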

Other observations

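All comparisons of this part were chosen after the data were seen, and none has a test.

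The series lay in the order of days since transplanting. The SD over probes of the difference in mean level was 0.423 between day 23 and day 44, 0.644 between day 23 and day 57 and 0.699 between day 23 and day 78. It was 0.411 between day 44 and day 57, which differ in planting and month, 0.480 between day 44 and day 78, which share the planting, and 0.301 between day 57 and day 78, which share the month. Probes more than 2-fold apart numbered 2950, 8202 and 9253 for the first 3 pairs and 2813, 4352 and 1325 for the others. Each pair of a July with an August series also carries the difference between their scan days. It was not taken out of these distances, so the order cannot be put down to days since transplanting alone.

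Probe families, told apart by the start of the probe ID, differed in their share of rhythmic members. Of the tested probes 29.0% were rhythmic in all 4 series among those starting with 44kb3, 27.7% with eAry2, 26.5% with eAry1 and 22.5% with maskBest. Among families of which no probe is in the authors' value table, the share was 29.0% of 221 with 44kb3Koshi, 20.0% of 460 with PPNTpc, 17.4% of 3274 with eAryKoshi, 17.2% of 1317 with PPNTnpc and 16.7% of 294 with Cuffnpc. The families also differed in the share of their sequences that passed the filter on background, from 78.2% for 44kb3 to 22.1% for Cuffnpc. Their median log2 intensity ran from 9.53 for 44kb3 to 6.92 for Cuffnpc. The shares of rhythmic probes were adjusted for neither.

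Probes that overlap on the same strand gave nearly the same daily curve, with a median correlation of 0.999 and peaks within 2 h in 99.3% of the 9240 pairs rhythmic in all 4 series. Of pairs that overlap on opposite strands, 19 were rhythmic in all 4 series, with a median correlation of -0.583, against 0.0305 over 2000 random pairs. The correlation was below 0 in 52.6% of the 19, so they went both ways. Of the 19, 42.1% peaked over 8 h apart and 36.8% within 2 h, against 31.0% and 20.8% of the random pairs.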
